A study of Oryza sativa with 4 samples.

How the data were processed

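Binding of an OsGRF6-GFP fusion was measured by ChIP sequencing in rice callus (1 ChIP library, 1 input library) and gene expression by RNA sequencing in panicles (1 MIM396 library, 1 wild-type library). Per the labels' protocols, crosslinked chromatin was fragmented by sonication and RNA libraries were made with a TruSeq kit. The submitters' processing notes name FastQC and Bowtie, without versions. The counting tool, the genome build and the annotation release are not given in the sources used here. Coordinates are printed as the authors' files give them. Of 231 transcripts in the peak table that are paired with an RGAP locus, 229 overlapped that locus's interval in the expression table, so both tables use 1 coordinate system.

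The expression table holds 55986 loci with FPKM per library, which the authors computed, and a read signal per library named as counts. FPKM by name means fragments scaled by locus length and library size, but the headers do not give the scaling used. The deposited signal values were gene read counts that the authors had multiplied by 1 factor per library: low values were whole multiples of 1.057 in wild type and 0.844 in MIM396. Dividing by that step gave values within 0.01 of a whole number for 97.8% of positive values in wild type and 99.0% in MIM396 (99.7% of those under 50 reads in each). These recovered reads total 16337503 in wild type and 13125598 in MIM396. The authors' factors raised the wild-type total to 1.727e+07 and lowered the MIM396 total to 1.108e+07, and FPKM summed to 849095 and 506480. The main comparison therefore does not bring the libraries to equal totals. With 1 library per group, a count test has no residual degrees of freedom and was not run, so no number of called genes is given from it. The table also holds the authors' FDR (a p-value adjusted for multiple tests, whose test is not given in the sources used here) and log2 ratios, and these are quoted as the authors' values only. The expression table lists 1722 loci whose interval is shared with another locus, 11 of them at peaks, so reads of overlapping genes may be divided between them, and whether counting used strand is not given in the sources used here.

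The peak table lists peaks with identifiers that begin with MACS, a peak caller, and for each peak the gene models that the authors placed at it: overlapping, within 1 or 3 kb upstream, or within 1 or 3 kb downstream. It gives positions only, and the height, fold and p of the peaks were not analysed here. Peaks came from 1 ChIP library, so there is no replicate peak set. The table pairs gene models of the RAP annotation with RGAP loci and with descriptions, and all 175 of its RGAP loci were found in the expression table. The reference table of gene names (assembly ASM3414082v1) matched 0 of the expression table's loci, so other loci carry no name here. For this reason the expression of the growth-regulating factors, planned as the first check of the labels, and lists over all genes were left out. Lists among peak genes were given as counts with no expected number, and a motif search was left out because no genome sequence was used here.

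Expression was compared as log2 of (MIM396 FPKM + 1) / (wild-type FPKM + 1), which understates differences of low loci. A locus was called higher or lower by size only, with a log2 ratio of at least 1 in either direction and a mean of at least 1 FPKM. For single loci, the ratio of scaled reads is given with a 95% exact conditional binomial (Clopper-Pearson) interval on the recovered reads. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Medians of lists and of loci at peaks were placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a place beyond the central 95% (below percentile 2.5 or above 97.5) describes these libraries and is not a test of genotype. Shares of peaks carry Clopper-Pearson intervals.

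The size rule, intervals and random lists were tested on simulated data: 20 pairs of Poisson libraries over the 27254 loci with reads, with 200 loci changed by known folds. At most 94 unchanged loci passed the size rule (mean 79.4), and 28.3%, 93.0%, 95.1% and 95.5% of loci changed 2-, 4-, 8- and 16-fold were recovered. The added 1 FPKM pulls a true 2-fold change under the limit, so the low share at 2-fold follows from the rule itself. Intervals held the true ratio in 95.7% of cases. Of 40 random sets without a shift, 37 lay inside the central 95%, and all 40 sets shifted by 1 on the log2 scale lay above it.

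The groups, the comparisons, the size rule, 31 gene lists searched in the annotation text, 19 panicle and meristem loci and the rule for named genes were fixed before the data were examined. The rule names the 8 described loci with the highest and the 8 with the lowest log2 ratio past the size rule with a mean of at least 5 FPKM, leaving out transposon, hypothetical and undescribed genes, and up to 4 members of each list, here among loci at peaks since only these carry descriptions. Where a list had more than 4 members above the floor, the fifth is given for completeness. Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no floor and a floor of 5 FPKM, a 3-fold limit, centring on the median, TMM scaling, unmatched random lists, other distances between peak and gene and a 1.5-fold limit at peaks. Alternatives chosen after seeing the data left out the 50 most abundant loci of each library, took the wider peaks, took peaks over the gene or within 1 kb upstream, left out peaks at organelle-like gene models, took loci near peaks that the authors do not list, brought the libraries to equal totals with all loci kept, left out the abundant loci with the authors' scaling, set the peak loci against unmatched random sets, and applied the rescalings to the peak loci and lists. TMM factors came from edgeR 4.0.16 in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.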

Results

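The series examined genes regulated by OsGRF6, a rice growth-regulating factor (a plant transcription factor family targeted by the microRNA miR396). It held 4 libraries, 1 in each of 4 groups. An OsGRF6-GFP ChIP library, precipitated with an anti-GFP antibody, and its ChIP input came from callus (cultured undifferentiated tissue) of lines that carry OsGRF6-GFP under the 35S promoter, a strong constitutive promoter. A MIM396 RNA library and a wild-type RNA library came from panicles, the rice inflorescence, at the stage of secondary branch development. MIM396 is a transgene that makes a decoy target RNA, which sequesters miR396, and the wild type was Yutai B. The wild-type library held 16337503 reads and the MIM396 library 13125598, as recovered from the scaled read counts, and 24720 and 24527 loci had at least 1 read. Depth of the ChIP and input libraries was not analysed here. With 1 library per group, no value has a replicate error and no difference between genotypes was tested, so each expression difference below describes 2 libraries. Intervals are 95% and cover counting error only.

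The binding data address where OsGRF6-GFP occupied the genome of callus cells. The authors' list held 142 peaks, numbered up to 200, at 214 RAP gene models, of which 178 were paired with 175 RGAP loci (locus names that begin with LOC_Os). The other 58 numbers were not analysed here, and every listed peak was placed within 3 kb of a gene model, so the shares below are of gene-assigned peaks and not of all called peaks. The peaks had a median width of 1182 bp, with a range of 578 to 3253 bp. A peak overlapped a gene in 83 cases, 58.5% of the peaks (49.9 to 66.7%, Clopper-Pearson), and lay within 1 kb upstream of a gene in 84 cases, 59.2% (50.6 to 67.3%), and 63 peaks did both for the same or another gene. Peaks were grouped by 1 placement each, with upstream placements ranked above downstream ones whatever the distance. By this ranking, 104 peaks lay over a gene or within 1 kb upstream, 27 lay 1 to 3 kb upstream and 11 lay downstream of genes only. A peak counted as upstream may lie nearer to another gene downstream. Peak 33, counted as 1 to 3 kb upstream of LOC_Os01g63230, lay within 1 kb downstream of LOC_Os01g63240. Chromosome 1 held 32 peaks, 22.5% of the list (15.95 to 30.3%), and 11.7% of the annotated loci on the 12 chromosomes. Chromosome 9 held 5 peaks, 3.52% (1.15 to 8.03%), against 6.11% of the loci.

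**Figure D1:**
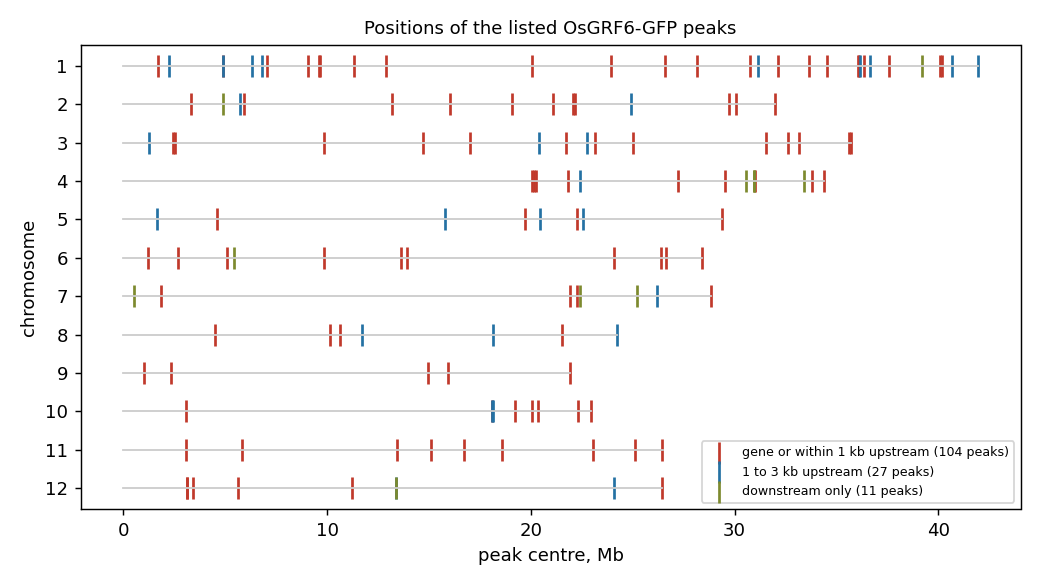
Centre of each of the 142 listed OsGRF6-GFP peaks (x axis, Mb, in the authors' coordinates) on the 12 rice chromosomes (y axis). Each tick is coloured by the placement of the peak relative to a gene, with upstream placements ranked above downstream ones. Grey lines run from 0 to the last peak of a chromosome and do not show its length; chromosome 1 has 32 ticks and chromosome 9 has 5.

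The genes at these peaks included some regulators of transcription and of auxin response. Of the 214 RAP genes, 15 had an annotation that names DNA binding or transcription. Peak 48 (chromosome 2, 21097267 to 21098565) overlapped LOC_Os02g35140, annotated as similar to auxin response factor 1, and peak 38 (chromosome 1, 40691932 to 40693106) lay 1 to 3 kb upstream of LOC_Os01g70270, similar to auxin response factor 2. Auxin response factors are DNA-binding proteins that control auxin-responsive genes. Peak 100 (chromosome 4, 33787200 to 33788561) lay downstream of LOC_Os04g56680, a member of the SAUR family of auxin-responsive proteins. Homeodomain-type genes were LOC_Os08g19590 at peak 140 (chromosome 8, 11698907 to 11699770) and LOC_Os10g33960, similar to Rolled leaf1, at peak 161 (chromosome 10, 18081431 to 18082649). LOC_Os11g06410 at peak 171 (chromosome 11, 3090669 to 3091918) was described as homeodomain-like only. A locus similar to Argonaute 4, a protein that binds small RNAs and acts in RNA-directed DNA methylation, had peak 13 (chromosome 1, 9638944 to 9640200) within 1 kb upstream. Of 31 gene lists fixed before the data were examined, 15 matched no gene at a peak in a search of the annotation text. These included the lists of growth-regulating factors, GRF-interacting factors, MADS-box, SBP-box and TCP factors, core histones and expansins. Such a search misses members described otherwise, and 82 of the 214 RAP genes were described as hypothetical or non-coding. LOC_Os07g37140, described as a WRC domain protein and overlapped by peak 131, matched no list. It had 15.2 FPKM in wild type and 18.9 in MIM396. These 15 lists are therefore not shown to be absent from peaks. Whether the other lists had more genes at peaks than chance gives was not computed, because gene descriptions were at hand for the peak genes only.

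The expression data address which genes differed between MIM396 and wild-type panicles. The most unequal loci with a mean of at least 5 FPKM spanned orders of magnitude. LOC_Os01g62260 had 0.132 FPKM in the wild-type library, from 2 reads, and 1138 FPKM in the MIM396 library, a ratio of 8523 (2359 to 70380). LOC_Os02g49720 had 0.498 and 1117 FPKM. In the other direction, LOC_Os01g41710 had 12170 FPKM in the wild-type library and 0.913 FPKM in the MIM396 library, and LOC_Os07g37240 had 8257 and 0.672 FPKM. The sources used here do not pair these 4 loci with a name or a function, and the same holds for the growth-regulating factor loci. The targets of miR396 were therefore not named here, and the genotype labels were not checked with them.

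Among 19456 loci with a mean of at least 1 FPKM, 4493 were at least 2-fold higher in the MIM396 library and 5310 at least 2-fold lower on the log2(FPKM + 1) scale, together 50.4% of those loci. A difference of at least 16-fold was seen for 363 loci higher and 974 loci lower. Under the authors' scaling the median log2 ratio was 0.00, with quartiles of -1.16 and 0.91. This median depends on the scaling, as given below, so 0.00 is not itself a finding about the panicles. Across loci, which are not independent replicates, log2(FPKM + 1) of the libraries had a Pearson r of 0.40 and a Spearman rho of 0.44. In simulated pairs of libraries with these depths, counting error alone took at most 94 unchanged loci past the same limits. The split depended on the scaling. With all loci kept and the libraries brought to equal totals, the median log2 ratio moved to 0.59 and 7315 loci were higher and 3900 lower. With the 50 most abundant loci of each library left out and the rest brought to equal totals, the median was 0.37 and 6061 loci were higher and 4304 lower. Leaving them out with the authors' scaling gave 4455 higher and 5264 lower, and TMM scaling of all loci 4515 and 5293. In the authors' deposited table, 2773 loci had an FDR under 0.05, 1094 of them higher and 1679 lower in MIM396, and 2631 of the 2773 were also past the 2-fold limit used here.

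The libraries differed in how reads were spread over loci. The 50 most abundant loci took 23.6% of the reads in the wild-type library (23.55 to 23.59%, Clopper-Pearson) and 11.4% in the MIM396 library (11.40 to 11.43%). Of the 50 most abundant loci of the wild-type library, 46 were at least 2-fold lower in MIM396 and 37 at least 100-fold lower. Of the 50 most abundant of the MIM396 library, 38 were at least 2-fold and 6 at least 100-fold higher than in wild type. In the wild-type library, 82 loci with at least 1000 reads had 3 or fewer reads in MIM396, and 54 loci showed the opposite. A set of 19 loci listed beforehand as panicle and meristem genes, whose identities rest on general knowledge and not on these files, had at least 1 FPKM at 15 loci in the MIM396 library and at 6 in the wild-type library. These features move with the genotype in every expression difference given here.

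**Figure D2:**
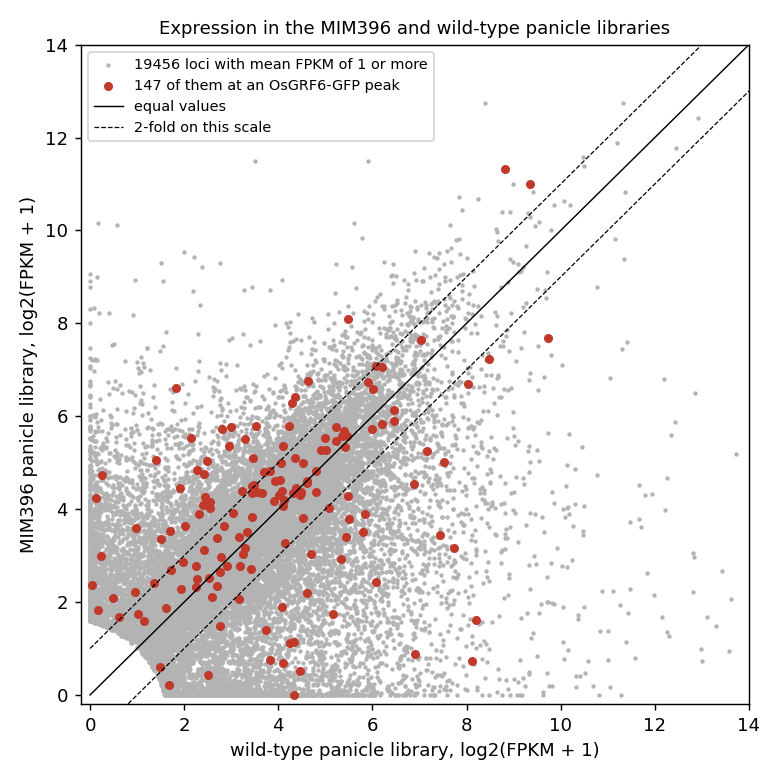
Expression of 19456 loci with a mean of at least 1 FPKM (grey points) in the wild-type panicle library (x axis) and the MIM396 panicle library (y axis), both as log2(FPKM + 1), with the 147 of them at a listed OsGRF6-GFP peak in red. The solid line marks equal values and the dashed lines a 2-fold difference; 4493 loci lie on or above the upper dashed line and 5310 on or below the lower one.

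Joining the peak list with the expression table addresses which genes placed at OsGRF6-GFP peaks differed between the panicle libraries. Placement reaches up to 3 kb upstream or downstream, so a locus at a peak is not thereby shown to be bound. Of the 175 loci at peaks, 147 had a mean of at least 1 FPKM, and 44 of these were at least 2-fold higher in the MIM396 library, 34 at least 2-fold lower and 69 neither. Among described loci with a mean of at least 5 FPKM, LOC_Os10g42610, a tetratricopeptide-like protein on chromosome 10 (22964272 to 22965575) that peak 169 overlaps (22965108 to 22966274), had 2.53 FPKM in wild type and 96.9 FPKM in MIM396, 38.1-fold higher in scaled reads (28.8 to 51.5). LOC_Os01g11710, an SGNH-type esterase with peak 7 (chromosome 1, 6316463 to 6317787) 1 to 3 kb upstream, had 0.199 and 25.7 FPKM, from 5 and 806 reads. The locus similar to Argonaute 4, LOC_Os01g16870, had 43.9 FPKM in wild type and 271.6 in MIM396, 6.16-fold higher (5.88 to 6.47). LOC_Os03g17690, similar to L-ascorbate peroxidase, an enzyme that removes hydrogen peroxide, was overlapped by peak 63 (chromosome 3, 9842814 to 9843617) and had 448.9 and 2569 FPKM, 5.67-fold higher (5.52 to 5.82). The other 4 of the 8 highest were LOC_Os01g63240, a reticulon family gene, at 9.86-fold, LOC_Os08g29600, similar to a seed maturation protein, at 7.39-fold, LOC_Os03g55470, a DUF566 family gene, at 7.26-fold, and LOC_Os10g35980, a tetraspanin gene, at 6.80-fold. Of these 4, LOC_Os01g63240 had a downstream peak only.

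Among the 8 described peak loci with the lowest ratios, LOC_Os03g36750, a haloacid dehalogenase-like hydrolase gene on chromosome 3 (20379625 to 20387042) with peak 66 (20388644 to 20389927) downstream, had 291.9 FPKM in wild type and 2.08 FPKM in MIM396, 141.5-fold lower (104.6 to 196.7). LOC_Os07g43800, which encodes an EF-hand protein of the calcium-binding type and has peak 135 (chromosome 7, 26206248 to 26207417) upstream, had 21.0 and 0.421 FPKM, from 242 and 6 reads. LOC_Os08g16570, similar to a predicted protein, was 27.1-fold lower (22.9 to 32.2) and LOC_Os04g52100, a methionine aminopeptidase-type gene, 17.6-fold lower (15.4 to 20.2). The peak at LOC_Os04g52100 lay 1 to 3 kb downstream. LOC_Os03g29850, similar to a metal transport protein and overlapped by peak 65 (chromosome 3, 17011075 to 17012399), had 66.1 and 4.42 FPKM. Peak 124 (chromosome 6, 26649121 to 26650373) overlapped LOC_Os06g44170, similar to a Helminthosporium carbonum susceptibility gene and 26.6-fold lower (15.6 to 49.2), and lay 1 to 3 kb upstream of LOC_Os06g44160, a DnaJ family gene and 16.2-fold lower (11.3 to 23.9). At peak 33 (chromosome 1, 36650399 to 36652116), LOC_Os01g63230, an O-fucosyltransferase domain gene, was 15.6-fold lower (11.8 to 21.1) while its neighbour, the reticulon family gene LOC_Os01g63240, was higher. The expression table gives LOC_Os01g63230 the same interval as another locus, so its reads are uncertain. Of these 16 loci, the authors' deposited table gave an FDR under 0.05 to LOC_Os10g42610 (0.0129) and LOC_Os01g11710 (0.000106) among the higher ones, and to each of the lower ones except LOC_Os06g44160 (0.155) and LOC_Os01g63230 (0.301).

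**Figure D3:**
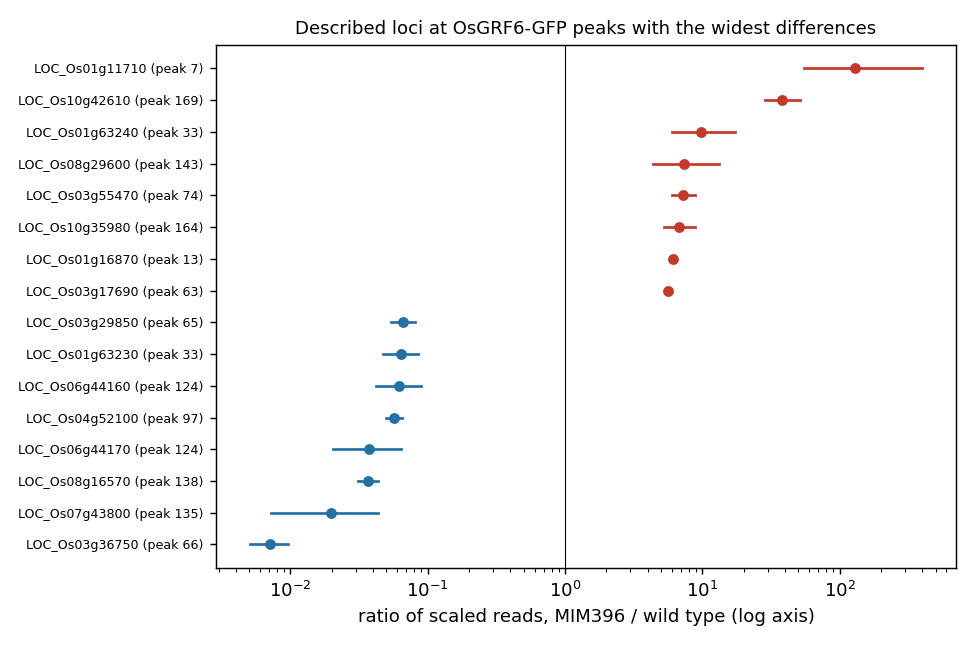
Ratio of scaled reads in the MIM396 library to those in the wild-type library (x axis, log scale) for the 16 described peak loci named by rule, with 95% exact conditional binomial intervals that cover counting error only. Red marks loci higher and blue loci lower in MIM396; they range from LOC_Os01g11710 (128.7) down to LOC_Os03g36750 (0.00706).

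Grouped by the fixed lists, 2 lists had 3 or more peak loci above the floor. The homeobox list had 5 such loci, 4 of them higher in MIM396, none lower and 1 neither. LOC_Os10g33960, similar to Rolled leaf1, an HD-ZIP factor of leaf polarity in maize, had 10.5 FPKM in wild type and 54.1 FPKM in MIM396, 5.15-fold higher (4.66 to 5.70). LOC_Os08g19590, described as a homeobox domain gene, had 8.75 and 44.6 FPKM. LOC_Os11g06410, described as homeodomain-like only, had 3.03 and 11.4 FPKM. The other members were taken in through their MYB-type homeodomain-like annotation: LOC_Os05g38460, similar to a Gag/env/c-myb protein, had 0.407 and 3.26 FPKM, and LOC_Os01g62410, an R1R2R3 MYB factor, 8.77 and 7.96 FPKM. The list's median log2 ratio was 1.62, the value of LOC_Os11g06410. It lay at percentile 98.0 of 10000 matched random lists, whose central 95% ran from -1.99 to 1.51. This place beyond the central 95% was lost with unmatched random lists (percentile 97.49) and with the 50 most abundant loci left out (97.23).

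The heat shock list had 4 such loci, 3 lower and 1 higher. The lower ones were the DnaJ family gene LOC_Os06g44160, with 34.9 FPKM in wild type and 2.33 in MIM396, LOC_Os02g52270, similar to the chaperone dnaJ, with 39.0 and 6.57 FPKM, and LOC_Os01g62290, an Hsp70 family gene, with 54.5 and 10.4 FPKM. LOC_Os01g62300, an HSP20-like chaperone gene next to the Hsp70 gene, was overlapped by peak 28 (chromosome 1, 36046037 to 36047450), which lay 1 to 3 kb downstream of the Hsp70 gene, and had 16.1 and 40.2 FPKM. The median of -2.34 lay at percentile 2.96, within the central 95% of matched random lists (-2.46 to 1.57), and at percentile 2.22 with unmatched lists and 2.39 with equal totals.

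Lists with fewer loci are given as values. Among the loci named in this paragraph, LOC_Os04g56680, LOC_Os07g36610, LOC_Os07g42170, LOC_Os04g52090, LOC_Os03g36750 and LOC_Os02g36520 had a downstream peak only. Of the auxin response factors, LOC_Os02g35140 had 19.4 FPKM in wild type and 84.4 in MIM396, 4.33-fold higher (4.04 to 4.65), and LOC_Os01g70270 had 63.6 and 95.6 FPKM, 1.497-fold (1.43 to 1.57). Both also carry the annotation searched for the Aux/IAA list, which had no other locus. The SAUR locus LOC_Os04g56680 had 0 reads in wild type and 25 in MIM396, a ratio whose 95% interval starts at 5.02, and its mean lay under 1 FPKM. LOC_Os07g36610, similar to the cellulose synthase-like gene CslF9, had 1 read in wild type and 205 in MIM396, a ratio of 163.7 (29.1 to 6497). LOC_Os08g17400, similar to WRKY transcription factor 44, had 56.5 and 13.98 FPKM, and its interval is shared with another locus. The ribosomal protein loci LOC_Os07g42170 and LOC_Os04g56670 had ratios of 2.02 (1.84 to 2.22) and 0.571 (0.471 to 0.692). LOC_Os04g52090, similar to the AP2-type factor RAP2.6, had 41.3 and 50.3 FPKM, and a second such locus, LOC_Os12g07030, lay under the floor with 0.981 and 0.488 FPKM. The peroxidase list held only the ascorbate peroxidase locus given above. A seed storage domain locus, LOC_Os01g42210, had 0.541 and 2.20 FPKM, from 4 and 20 reads, and an NBS-LRR list member, LOC_Os11g10610, had 0 reads in both libraries. The lists of ALOG proteins, cyclins, root and pollen genes matched 2, 2, 1 and 1 loci whose descriptions name other functions, among them the hydrolase LOC_Os03g36750, the F-box gene LOC_Os01g59690 (6.79 and 40.2 FPKM) and the Kelch-type gene LOC_Os02g36520 (8.03 and 3.20 FPKM).

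As a set, the 147 expressed loci at peaks had a median log2 ratio of 0.28, at percentile 98.5 of 10000 random sets of loci matched on mean expression, whose central 95% ran from -0.30 to 0.25. The matched sets held a median of 33 loci higher in MIM396 (23 to 43), against 44 at peaks, and 42 lower (32 to 52), against 34 at peaks. The 89 loci with a peak over the gene or within 1 kb upstream had a median of 0.27 (percentile 94.6), the 30 with a peak 1 to 3 kb upstream 0.74 (percentile 99.5) and the 28 with a downstream peak only -0.06 (percentile 46.8). The place of the whole set beyond the central 95% was lost when only peaks within 1 kb upstream counted (76 loci, percentile 96.4), with the wider peaks only (75 loci, 90.3) and with the 50 most abundant loci of each library left out and the rest rescaled (97.46). With equal totals over all loci, 68 peak loci were higher and 27 lower, with a median of 0.88 at percentile 97.72. Loci that share a peak were counted separately, and 27 peaks had at least 2 expressed loci. The random sets drew single loci without regard to neighbours. Their central 95% therefore does not allow for neighbouring loci that change together. Binding was measured in callus and expression in panicles, with 1 library each.

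**Figure D4:**
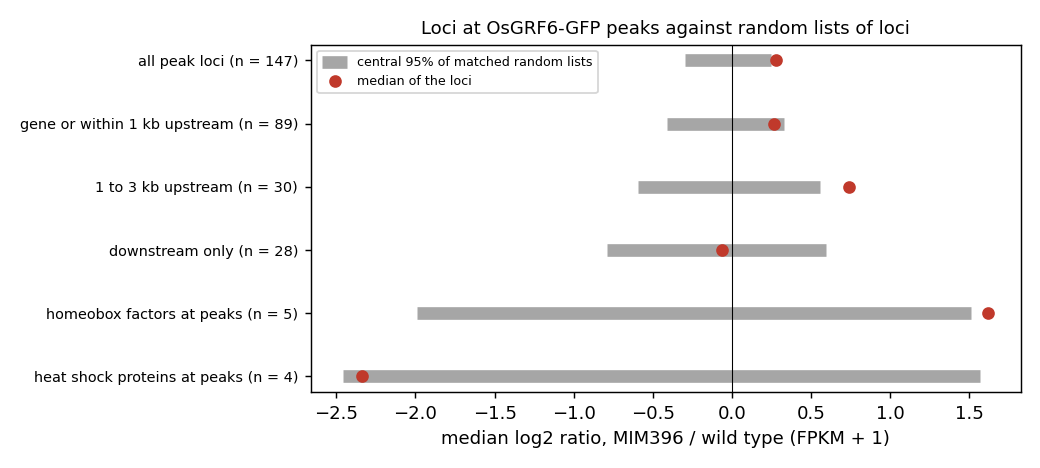
Median log2 ratio of MIM396 to wild type on FPKM + 1 (x axis, red points) for the expressed loci at OsGRF6-GFP peaks, for the same loci by placement of the peak, and for the lists with at least 3 loci. Grey bars span the central 95% of medians of 10000 random lists of the same size matched on mean expression. The points for all peak loci (0.28), for peaks 1 to 3 kb upstream (0.74) and for the homeobox list (1.62) lie beyond the bars. The homeobox list was taken by annotation text and includes MYB-type loci. The places of all peak loci and of this list were lost under some other settings.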

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

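The alternatives that leave out the 50 most abundant loci, take the wider peaks, take peaks over the gene or within 1 kb upstream, leave out organelle-like peaks, bring all loci to equal totals, take unlisted loci near peaks, or apply TMM scaling to peak loci and lists were chosen after the data were seen. No paired analysis was possible because each genotype has 1 library. The number of loci higher in MIM396, 4493, became 2731 with a pseudocount of 5 and 2829 with a 3-fold limit, both stricter by construction, and 7315 with equal totals over all loci, which raises every ratio, and the other counts of higher or lower loci stayed within 1.5 times of the main ones. For loci at peaks, counting only peaks within 1 kb upstream gave percentile 96.42 with 26 loci higher and 15 lower, the wider peaks gave percentile 90.27 with 21 higher and 23 lower, and peaks over the gene or within 1 kb upstream gave 94.61 with 28 higher and 19 lower, and the loci near peaks that the authors do not list gave 77.78 with 11 higher and 10 lower. These use fewer loci, which lowers the counts, and the cause of the lower percentiles was not tested. With the 50 most abundant loci left out and the rest rescaled, the peak loci had a median of 0.64 at percentile 97.46. With equal totals over all loci, they had a median of 0.88 with 68 higher, at percentile 97.72. Both rescalings shift every locus upward, but the cause of the lower percentile was not tested. The homeobox median became 2.34 with a pseudocount of 0.1, as low loci are then less damped, and its percentile 97.49 with unmatched lists and 97.23 with the most abundant loci left out, while that of the heat shock list became 2.22 with unmatched lists and 2.39 with equal totals. The cause was not tested. Of 114 alternative values for single named loci, 0 changed direction and 41 moved by more than their counting error, such as LOC_Os01g11710, from a log2 ratio of 4.48 to 2.56 with a pseudocount of 5 and 6.43 with 0.1. Leaving out organelle-like peaks removed no expressed locus and so tests nothing. Not run were alternatives ranked by peak score, those for the growth-regulating factors, the motif, and the background of lists among peak genes, for the reasons given with the processing. Depth limits ratios that rest on few reads, such as that of LOC_Os01g62260 with 2 reads in wild type, whose interval runs from 2359 to 70380.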

Other observations

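Most values in the first paragraphs of this part were picked out after the data were seen. In the weighing that follows, the tests of the 19 panicle loci, of the most abundant loci, of expression level, of unlisted loci and of peak position were chosen after the data were seen.

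Abundant ubiquitin genes at peaks went opposite ways. LOC_Os02g06640, similar to polyubiquitin and overlapped by peak 40 (chromosome 2, 3343028 to 3344107), had 648.6 FPKM in wild type and 2062 FPKM in MIM396, 3.18-fold higher (3.12 to 3.23). LOC_Os06g46770, a ubiquitin domain gene overlapped by peak 125 (chromosome 6, 28400090 to 28401936), had 845.8 and 204.5 FPKM, 4.15-fold lower (4.03 to 4.26). On chromosome 10, peaks 161, 162 and 163 were separated by 23949 and 24957 bp, and a locus at each was higher in MIM396: LOC_Os10g33960, similar to Rolled leaf1, LOC_Os10g33970, a double-stranded RNA-binding-like gene (10.2 and 22.0 FPKM), and LOC_Os10g33990, a hypothetical conserved gene (7.004 and 53.6 FPKM). Of 27 peaks with at least 2 expressed loci, 4 had loci in both directions, 1 had 2 or more higher and none lower, and 3 had 2 or more lower and none higher.

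The widest peak, number 185 with 3253 bp (chromosome 12, 5612388 to 5615640), lay at gene models described by the chloroplast genes for ATP synthase and Rubisco subunits, and peaks 195 and 196 on the same chromosome lay near models described as a NADH dehydrogenase subunit. No explanation was tested for them.

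The authors' FDR treated zeros apart from low counts. In the authors' deposited table, 5263 loci had 0 reads in one library, 491 of them with at least 100 reads in the other, and 0 of the 5263 had an FDR under 0.05; the lowest was 0.0754. Of 250 loci with 1 read in one library and at least 100 in the other, 244 (97.6%) had an FDR under 0.05. The deposited calls therefore leave out loci detected in 1 library alone.

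About as many loci differed at least 2-fold between the panicle libraries as did not. Scaling and a few very abundant loci are argued against as the cause by the spread of the log2 ratios, with quartiles of -1.16 and 0.91. A rescaling moves most ratios alike and does not narrow that spread. With the 50 most abundant loci of each library left out and the rest rescaled, 10365 loci were past the limits. Of these, 8759 were past them in the same direction under the authors' scaling. These counts follow from the same spread and are not separate evidence. Counting error is also argued against, as it took at most 94 loci past the limits. A hypothesis is that the wild-type library may hold less RNA of panicle meristems than its label implies. Of the 19 prelisted loci, 6 had at least 1 FPKM in the wild-type library and 15 in MIM396, and the median log2 ratio of the 15 above the floor was 3.34, above every matched random list (central 95% from -1.32 to 0.87). With 1 library per genotype, tissue, stage or label cannot be told apart from an effect of MIM396, which stays open, and the identities of the 19 loci were not checked against these files.

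Loci at OsGRF6-GFP peaks had a higher median log2 ratio than other loci. For the full set of peak loci, expression level alone is argued against. Random sets matched on it had a median of -0.011 and the peak loci 0.28 (bootstrap interval 0.07 to 0.59). The bootstrap treated loci that share a peak as independent. With peaks within 1 kb upstream only, the lower bound was -0.038 and the matched median -0.023. With peaks over the gene or within 1 kb upstream, these were -0.0193 and -0.0181, and with the wider peaks -0.124 and -0.012. In these smaller sets the same comparison does not argue against expression level. Chance is not excluded, as 4 other settings put the peak loci at percentiles 90.27 to 97.46, inside the central 95%. The authors' choice of gene models stays open: the 43 expressed loci within 5000 bp of a peak that they do not list had a median of 0.18 at percentile 77.78, too few to decide. A hypothesis is that the place of the peak matters: the 119 loci with a peak over the gene or upstream had a median of 0.45 and the 28 with a downstream peak only -0.06, a difference at percentile 97.07 of 10000 random reassignments, which is inside the central 95% used elsewhere. The highest median was at peaks 1 to 3 kb upstream and not at the nearest ones, so this may also be chance, and the difference of the panicle libraries described above stays open as a source. None of the 19 panicle loci lay within 5000 bp of a listed peak, and the nearest was 64.9 kb away. Of all 55986 loci, 303 lay within that distance. With so small a share, 19 loci are too few to show whether panicle genes lack peaks.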
